A study of Homo sapiens with 12 samples.

How the data were processed

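RNA was measured by poly-T-selected RNA sequencing in 12 libraries of HepG2 cells, a human hepatoma line widely used as a liver cell model. Per the labels, cells received 0.1% DMSO as the vehicle control, or 100 µM of perfluorooctanoic acid (PFOA), perfluoroundecanoic acid (PFUnDA) or hexafluoropropylene oxide dimer acid (HFPODA), for 48 h, with 3 libraries per group. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The design text also describes mouse and macrophage experiments, which were not analysed here.

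The authors deposited 1 table per compound, each with that compound's 3 libraries beside the same 3 control libraries. Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0 on the human build hg38. Their settings, and whether counting used strand, are not given in the sources used here. The deposited per-library values are a normalized signal: gene counts that the authors divided by 1 size factor per library, set separately in each table, as the values themselves show. The authors' tables also give a log2 fold change of compound over control, and a p-value with an adjusted p-value, per the file headers. The adjusted value equals 1 for 46.7% to 52.5% of the genes in these tables. Gene symbols and coordinates (hg38, counted from 1) are those of the deposited tables. Deposited tables of KEGG pathway enrichment give the number of genes the authors entered per pathway with a p-value, and the tool behind them is not given in the sources used here. All columns of per-library values matched 1 sample's labels, so 0 were left unmapped.

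The step between low values in each of the 18 per-library columns gave its size factor, and 100% of the values came out as whole reads within 1e-06 of a read. The control reads recovered in this way differed between tables in 0 values over the 23292 genes that all 3 tables hold. Recovered totals ran from 13029730 to 15379426 reads per library. The recovery step was tested on simulated columns with known size factors and returned 100% of the reads in each of 5 columns. No pair of replicates agreed within sampling noise (chi-square per degree of freedom from 5.41 to 48.7), so every library was counted as its own sample.

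Each compound was compared with control within its own table. Genes with a value of at least 10 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend, on log2(value + 1). Fold changes are on that scale, which understates the change of low genes. Compounds were compared with one another in 1 model with 4 group means over all 12 libraries, on recovered reads scaled by size factors computed jointly (median of ratios), since the deposited scaling differs between tables. Levels set side by side across compounds come from this joint scaling. The 12-library model gives each gene 1 spread for all 4 groups, so a wider spread in 1 group is averaged with that of the others. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The design written before the data were examined named edgeR for count tables and limma for normalized values, and the deposited unit called for limma. The gene lists, the panel, the rule for named genes and most of the alternative settings were also fixed before the data were examined. edgeR 4.0.16 on the recovered reads was added afterwards and called 1934 genes for PFOA, 973 for PFUnDA and 0 for HFPODA against control, 444 for PFUnDA against PFOA, 270 for HFPODA against PFOA and 1458 for HFPODA against PFUnDA.

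The gene lists covered PPAR alpha target genes, beta-oxidation enzymes, cholesterol synthesis and uptake (SREBP2) genes, fatty acid and triglyceride synthesis, lipid droplets and lipolysis, apolipoproteins, bile acids, xenobiotic metabolism, NRF2 oxidative stress genes, the integrated stress response (ATF4), the endoplasmic reticulum unfolded protein response, p53 targets, the cell cycle, inflammatory genes, the acute phase, hepatocyte identity, glucose metabolism, hypoxia, extracellular matrix, macrophage and leukocyte markers, endothelial and cholangiocyte markers, mitochondrially encoded messenger RNA, and heat shock proteins with metallothioneins. They were tested with camera in limma, which compares the genes of a list with all other genes, with the correlation between genes preset at 0.01 and adjustment over the 22 lists that had at least 5 tested genes. Of the 20 macrophage and leukocyte markers, 10 were in any table and fewer than 5 passed the filter, so that list has no test. Camera with an estimated correlation was run beside it.

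Genes were named by a fixed rule. It takes the 8 largest rises and the 8 largest falls against control (5 and 5 between compounds) among protein-coding genes with an adjusted p under 0.05, a mean of at least 50 and non-overlapping groups. It adds up to 4 members with the smallest adjusted p of each list past its threshold, and a panel of 24 lipid, stress and liver genes whose values may be given whatever their result. PDK4, CYP3A4 and FGF21 of the panel did not pass the filter on low values. Any other gene named was chosen after its values were seen, and is marked so. Values are means ± SD of 3 libraries in normalized reads.

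Each test was checked on simulated data in which 200 genes were changed by known folds. In the simulation of PFOA against control (13868 genes), limma recovered 47.8% of genes changed 1.5-fold, 68.7% changed 2-fold and 95.5% changed 4-fold. The same folds gave 43.3%, 74.6% and 98.5% for PFUnDA against control (13762 genes), and 23.9%, 74.6% and 92.4% for HFPODA against control (13799 genes). They gave 40.3%, 64.2% and 97.0% for PFUnDA against PFOA (14500 genes), 32.8%, 86.6% and 92.4% for HFPODA against PFOA (14490 genes), and 49.3%, 74.6% and 97.0% for HFPODA against PFUnDA (14513 genes). Between 3.25% and 7.36% of the simulated limma calls were of unchanged genes, and between 3.87% and 9.82% of those of edgeR. In the list test, 0 of 5 unshifted simulated lists were called in any comparison. The simulated genes were drawn independently and the lists at random, so this does not check the preset correlation for lists of co-regulated genes. All simulated libraries shared 1 dispersion per gene, and none stood apart. The simulated shares therefore do not check the tests where 1 library or group has a wider spread, as in HFPODA.

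The alternative settings fixed in advance were other scalings (RLE and upper quartile in edgeR), DESeq2 1.42.0, limma-voom, other filters and pseudocounts (0.1 and 10), protein-coding genes alone, a minimum fold, the replicate number as a covariate, another choice of libraries in the model, and leaving out each library in turn. TMM scaling, array quality weights, edgeR without mitochondrial genes and edgeR without HFPODA replicate 1 were added after the data were seen, as were the 2 pseudocounts and a filter at 50 for the comparisons between compounds. Reads shared between near-identical copies, overlapping genes or antisense partners were not measured, and values of AKR1C, CYP3A, metallothionein 1 and GOLGA8 genes are given with that limit.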

Results

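The transcriptome of HepG2 hepatoma cells was read in 12 libraries, 3 for the vehicle control and 3 for each of PFOA, PFUnDA and HFPODA at 100 µM for 48 h. PFOA is a perfluorinated carboxylic acid, PFUnDA is its longer-chain homologue, and HFPODA is an ether carboxylic acid that came into use as a substitute for PFOA. The series concerns the effect of such perfluoroalkyl substances on liver lipid metabolism, so the comparisons ask which transcripts each acid changed and how the acids differed. Libraries held 14706271 to 15366416 reads in control, 13801065 to 14637488 in PFOA, 14809043 to 15379426 in PFUnDA and 13029730 to 14715754 in HFPODA. Mitochondrially encoded messenger RNA took 4.04% ± 0.117 (SD, n = 3) of reads in control, 2.80% ± 0.178 in PFOA and 3.19% ± 0.263 in PFUnDA. In HFPODA the share was 0.583% in replicate 1, 3.19% in replicate 2 and 2.28% in replicate 3, so replicate 1 stood apart. ALB, which encodes serum albumin, took 2.23% ± 0.322 of reads in control.

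PFOA raised PLIN2, CPT1A and genes of cholesterol synthesis. PLIN2, a lipid droplet coat protein (ENSG00000147872, hg38 chromosome 9, 19108375 to 19149290), rose from 5611 ± 331 to 11620 ± 744 normalized reads (SD, n = 3), 2.07-fold. CPT1A, which commits fatty acids to mitochondrial import (ENSG00000110090, chromosome 11, 68754620 to 68844410), rose from 313 ± 62.2 to 621 ± 23.5, 2.00-fold. HMGCS1, at the start of cholesterol synthesis (chromosome 5, 43287470 to 43313512), rose from 2998 ± 166 to 4439 ± 124. Their log2 fold changes were 1.05 (SE 0.06), 1.00 (SE 0.13) and 0.57 (SE 0.05), with limma adjusted p of 0.000153, 0.00182 and 0.000499.

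Of 18 tested PPAR alpha target genes, 6 rose with PFOA and 0 fell (6 and 1 adjusted over the list alone). Beyond PLIN2 and CPT1A, ACADVL, the very long-chain acyl-CoA dehydrogenase, went from 2426 ± 45.0 to 3569 ± 99.3, and FABP1, the liver fatty acid carrier, from 3935 ± 122 to 5857 ± 496. The list passed its test with a median log2 fold change of 0.19 (camera adjusted p = 0.00805, and adjusted p = 0.203 with an estimated correlation). PPARA itself fell by 0.36, from 1870 ± 41.1 to 1465 ± 126 (limma adjusted p = 0.00950). Of 23 beta-oxidation enzymes 6 rose (8 up and 1 down adjusted over the list alone), among them ACAA2 (0.32) and ECI1 (0.31), with a list median of 0.10 (camera adjusted p = 0.0197, and adjusted p = 0.620 with an estimated correlation). That list no longer passed without PFOA replicate 1 (camera adjusted p = 0.117), control replicate 1 (0.0712) or control replicate 3 (0.0610).

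Cholesterol synthesis and uptake genes moved with PFOA as well, 11 of 22 up and 0 down (13 and 1 adjusted over the list alone). FDPS, which makes farnesyl diphosphate, went from 1373 ± 23.9 to 1723 ± 16.6, MVD from 1789 ± 124 to 2376 ± 64.6, and MSMO1 from 2603 ± 48.6 to 3210 ± 179. Over the list the median was 0.21 (camera adjusted p = 2.0e-05, and adjusted p = 0.203 with an estimated correlation). SREBF1, a regulator of lipid synthesis, rose by 0.36 on the log2 scale (limma adjusted p = 0.00447). FASN (0.08, 95% interval -0.02 to 0.19) and SCD (0.07, -0.04 to 0.18) did not pass the test.

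Mitochondrially encoded messenger RNAs fell with PFOA, 12 of 13 (13 adjusted over the list alone). MT-CO1, a subunit of cytochrome c oxidase (mitochondrial chromosome, 5904 to 7445), dropped from 161150 ± 4380 to 97368 ± 2542, and MT-CYB from 49135 ± 2235 to 29622 ± 1882. Their median was -0.67 (camera adjusted p = 5.9e-11, and adjusted p = 0.295 with an estimated correlation). Cell cycle genes rose in 10 of 25 cases (15 adjusted over the list alone). They included MCM7, part of the replicative helicase, from 3550 ± 217 to 4544 ± 39.0, and RRM2, a subunit of ribonucleotide reductase, from 2153 ± 122 to 2789 ± 140. Their median was 0.20 (camera adjusted p = 3.9e-06, and adjusted p = 0.361 with an estimated correlation), whereas the proliferation marker MKI67 read 0.08 (95% interval -0.08 to 0.24). Of 17 hypoxia response genes 7 rose (8 adjusted over the list alone). PFKFB4, a regulator of glycolysis, went from 448 ± 20.1 to 715 ± 21.0, and PDK1, which restrains pyruvate oxidation, from 708 ± 33.3 to 1082 ± 37.0. The hypoxia list had a median of 0.36 (camera adjusted p = 0.00393, and adjusted p = 0.371 with an estimated correlation).

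Inflammatory genes fell with PFOA in 4 of 12 cases (4 adjusted over the list alone), led by CX3CL1, the chemokine fractalkine, from 4844 ± 449 to 2581 ± 190, and NFKB1, from 1444 ± 29.9 to 1136 ± 23.4. The list median was -0.27 (camera adjusted p = 0.00119, and adjusted p = 0.203 with an estimated correlation). Among 20 p53 target genes 6 fell (7 adjusted over the list alone), including TP53INP1, from 901 ± 91.6 to 467 ± 55.7, and CDKN1A, the p21 cell cycle inhibitor, from 1157 ± 83.6 to 861 ± 69.0. Their median was -0.17 (camera adjusted p = 0.00322, and adjusted p = 0.336 with an estimated correlation). Xenobiotic metabolism genes fell in 4 of 10 cases (4 adjusted over the list alone; median -0.43, camera adjusted p = 0.00782, and adjusted p = 0.203 with an estimated correlation). CYP1A1, a target of the aryl hydrocarbon receptor, dropped from 113 ± 28.9 to 45.7 ± 7.99, and the drug efflux pump ABCB1 from 1387 ± 76.1 to 1071 ± 28.1. Unfolded protein response genes fell in 7 of 19 cases (9 adjusted over the list alone; median -0.17, camera adjusted p = 0.00471, and adjusted p = 0.370 with an estimated correlation), with SEL1L, of endoplasmic reticulum-associated degradation, going from 2248 ± 53.9 to 1880 ± 70.7.

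Hepatocyte identity genes fell in 6 of 20 cases and rose in 1, CEBPA, which was chosen after its values were seen (0.27; 7 down and 1 up adjusted over the list alone). FOXA3, a liver transcription factor, went from 1103 ± 77.6 to 827 ± 19.4. ALB (chromosome 4, 73397114 to 73421482) dropped from 336150 ± 51895 to 206800 ± 37281, a log2 fold change of -0.70 (limma adjusted p = 0.0130, and 0.0588 without PFOA replicate 2). The list had a median of -0.09 (camera adjusted p = 0.0194, and adjusted p = 0.203 with an estimated correlation), and its call ended without PFOA replicate 1 (0.0557). The NRF2 list went both ways, with 2 of 22 genes up and 6 down (2 and 7 adjusted over the list alone). HMOX1, which degrades heme, rose from 532 ± 44.4 to 807 ± 37.8, as did PGD of the pentose phosphate pathway (0.18; chosen after its values were seen). The aldo-keto reductases AKR1C1 and AKR1B10 dropped by 1.11 and 1.02 on the log2 scale, and reads shared between AKR1C1 and its near-identical paralogs were not measured. The NRF2 median was -0.12 (camera adjusted p = 0.0197, and adjusted p = 0.579 with an estimated correlation), and the call ended without PFOA replicate 3 (0.0543) or control replicate 2 (0.0755).

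The largest rises with PFOA were of CUTA, RNH1 (the ribonuclease inhibitor), FLII, HAL, CYP24A1, PABPC1L, LHFPL5 and GOLGA8B. CUTA (chromosome 6, 33416442 to 33418317) went from 32.6 ± 14.8 to 1449 ± 160, a log2 fold change of 5.51 (SE 0.26). HAL, the histidine ammonia-lyase, went from 53.1 ± 11 to 190 ± 44.3, and CYP24A1, the vitamin D 24-hydroxylase (chromosome 20, 54153446 to 54173986), from 206 ± 49.8 to 592 ± 41.9. The largest falls were of GLP2R, CLSTN3, HOXD1, PLAU (urokinase), C7, ANK2, ACACA and CNNM1. HOXD1, a homeobox factor (chromosome 2, 176188668 to 176190907), dropped from 248 ± 47.7 to 63.2 ± 4.52, and the complement component C7 from 148 ± 20.1 to 39.8 ± 8.67. In 6 of these 16 genes, CUTA, RNH1, FLII, GLP2R, CLSTN3 and ACACA, values also ranged within another compound's group by at least 90% of the PFOA fold change. Within the groups compared, ACACA ranged by 1.49 in PFOA (fold change -1.52) and FLII by 1.93 in control (1.97), on the log2 scale. RNH1 ranged by 2.59 (2.91) and GLP2R by 2.47 (-3.12) in PFOA. CUTA (5.51) and CLSTN3 (-2.58) ranged by at most 1.23 and 1.27 in those groups. Calls ended when single libraries were left out for FLII (limma adjusted p up to 0.106, without PFOA replicates 2 or 3) and PLAU (0.0568, without PFOA replicate 2). They also ended for LHFPL5 (up to 0.0902, without any of PFOA replicates 1, 2 and 3 or control replicates 2 and 3) and ACACA (up to 0.0682, without PFOA replicates 2 or 3 or control replicates 1 or 3). GOLGA8B has near-identical relatives, and reads shared with them were not measured.

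In all, limma called 2006 of 13869 genes for PFOA against control, 731 up and 1275 down, of which 175 changed by at least 1 on the log2 scale, and 1239 with all 12 libraries in the model. Groups did not overlap in 35.5% of genes, where chance gives 10%. With upper-quartile scaling in edgeR the split was 1077 up and 911 down, so the excess of falls depended on the scaling. Without PFOA replicate 2 the count was 927, without PFOA replicate 3 it was 1240 and without control replicate 3 it was 901. Of 77 genes named for this comparison or held in the panel, 17 lost their call in at least 1 fit that left out a library. Those 77 include panel genes that were not called, which had no call to lose. The authors' deposited table has 1923 genes past an adjusted p of 0.05, and 1719 of them were among the 2006. In the authors' deposited table of pathways, DNA replication held 20 of the 1616 genes entered, 20 of them up (adjusted p = 0.00506), and protein processing in the endoplasmic reticulum held 61, of which 56 were down (adjusted p = 0.00506). For PFUnDA and HFPODA more genes were entered than passed an adjusted p of 0.05, so the 1616 need not be drawn from the 1923.

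The other 10 lists did not pass the camera test for PFOA. Fatty acid and triglyceride synthesis had a median of 0.08 (adjusted p = 0.0555), lipid droplets and lipolysis 0.29 (0.102), apolipoproteins -0.05 (0.531), bile acids -0.06 (0.562) and endothelial and cholangiocyte markers -0.11 (0.562). Acute phase genes had 0.21 (0.578), with 5 up and 3 down of 13. Extracellular matrix genes had 0.04 (0.689), with a mean near 0 and a test directed down, and heat shock genes 0.06 (0.812) with a mean of -0.06. Glucose metabolism (0.03, mean -0.03) and ATF4 genes (0.02, mean -0.03, test directed down) each had a camera adjusted p of 0.879.

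PFUnDA changed fewer transcripts than PFOA, and neither PLIN2 nor CPT1A was among them. PLIN2 was 4909 ± 354 against 5675 ± 338 in control (SD, n = 3; log2 fold change -0.21, 95% interval -0.36 to -0.06, limma adjusted p = 0.0887), and CPT1A was 403 ± 72.7 against 317 ± 62.8 (0.35, -0.01 to 0.72, 0.226). G6PC1, the last enzyme of glucose production (ENSG00000131482, chromosome 17, 42900797 to 42914438), fell from 319 ± 46.4 to 123.3 ± 22.3, 2.58-fold. CCL20, a chemokine (chromosome 2, 227805739 to 227817564), fell from 2155 ± 487 to 855 ± 208, and DUSP6, a phosphatase of ERK (chromosome 12, 89347235 to 89352501), from 1911 ± 251 to 705 ± 87.0. ABCC3, an efflux pump for organic anions (chromosome 17, 50634777 to 50692253), rose from 645 ± 20 to 1232 ± 81.7 (log2 fold change 0.93, SE 0.06, limma adjusted p = 0.000327).

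Inflammatory genes fell with PFUnDA in 4 of 12 cases (11 adjusted over the list alone). Beside CCL20, TNFAIP3, an inhibitor of NF-kB signalling, went from 1302 ± 154 to 844 ± 69.7, and CX3CL1 from 4900 ± 456 to 3344 ± 467 (limma adjusted p = 0.0173, and 0.0809 without control replicate 3). The list median was -0.32 (camera adjusted p = 3.1e-05, and adjusted p = 0.163 with an estimated correlation). Unfolded protein response genes fell in 7 of 19 cases (12 adjusted over the list alone; median -0.24, camera adjusted p = 8.6e-05, and adjusted p = 0.556 with an estimated correlation). The chaperone HSP90B1 dropped from 17035 ± 579 to 13906 ± 233, and the transcription factor XBP1 from 6403 ± 240 to 5343 ± 219. Without control replicate 3 the limma adjusted p was 0.0625 for HSP90B1 and 0.0879 for XBP1. Xenobiotic metabolism genes fell in 3 of 10 cases (6 adjusted over the list alone; median -0.38, camera adjusted p = 0.000745, and adjusted p = 0.556 with an estimated correlation), with the sulfotransferase SULT2A1 going from 2298 ± 81.3 to 1741 ± 90.4. HMOX1 rose from 538 ± 44.8 to 834 ± 35.0 (limma adjusted p = 0.00252).

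Cell cycle genes rose in 5 of 25 cases with PFUnDA (8 adjusted over the list alone), 4 of them helicase subunits. MCM5 went from 2149 ± 146 to 3148 ± 192, and MCM7 (chromosome 7, 100092233 to 100101940) from 3591 ± 219 to 4792 ± 207. All 25 fold changes were above 0, with a median of 0.16 (camera adjusted p = 3.1e-05, and adjusted p = 0.569 with an estimated correlation). Glucose metabolism genes fell in 3 of 17 cases (4 adjusted over the list alone; median -0.11, camera adjusted p = 0.0284, and adjusted p = 0.556 with an estimated correlation), and that call ended without PFUnDA replicate 3 (0.133). Besides G6PC1, the glucose transporter SLC2A1 dropped from 17423 ± 2742 to 11055 ± 948 (limma adjusted p = 0.0120, and 0.0637 without control replicate 3). Hypoxia response genes fell in 3 of 17 cases (5 adjusted over the list alone), including P4HA1, a collagen prolyl hydroxylase, from 2380 ± 143 to 1754 ± 88.9, and NDRG1, from 2852 ± 39.4 to 2021 ± 213. That list (median -0.09, camera adjusted p = 0.0190, and adjusted p = 0.569 with an estimated correlation) was not called without PFUnDA replicate 3 (0.134) or control replicate 3 (0.0820).

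Of 22 cholesterol genes 1 fell with PFUnDA, SC5D, from 1794 ± 25.8 to 1298 ± 94.6 (1 adjusted over the list alone). This list had a median of -0.08 (camera adjusted p = 0.0282, and adjusted p = 0.569 with an estimated correlation), and the call ended without PFUnDA replicate 3 (0.231) or control replicate 1 (0.0796). Among PPAR alpha targets ANGPTL4, an inhibitor of lipoprotein lipase, went from 37.6 ± 2.22 to 15.6 ± 4.06, a log2 fold change of -1.25 (limma adjusted p = 0.0314). That call held without PFUnDA replicate 1 and ended without each of the other 5 libraries (PFUnDA replicates 2 and 3 and control replicates 1, 2 and 3), with an adjusted p of up to 0.113. The PPAR alpha list itself had a median of 0.02, a mean of -0.06 and a test directed down (camera adjusted p = 0.592).

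Mitochondrial transcripts moved in opposite directions with PFUnDA. Of 13 messenger RNAs 7 fell (8 down and 1 up adjusted over the list alone), with MT-CO1 going from 163010 ± 4459 to 90671 ± 7525 and MT-CO2 from 59883 ± 1450 to 42856 ± 2231. Over the 13 the median was -0.28 (camera adjusted p = 0.000593, and adjusted p = 0.569 with an estimated correlation). The ribosomal RNA MT-RNR1 (mitochondrial chromosome, 648 to 1601), chosen after its values were seen, rose from 17425 ± 1116 to 40010 ± 3350 (log2 fold change 1.198, SE 0.07, limma adjusted p = 0.000221). With PFOA, MT-RNR1 rose by 0.52 (limma adjusted p = 0.00258), and with HFPODA it read -0.50 (0.340). The more abundant MT-RNR2 read -0.12 with PFOA (limma adjusted p = 0.402), 0.47 with PFUnDA (0.0172) and -0.75 with HFPODA (0.202). These libraries were selected for poly(A) tails, and how much ribosomal RNA passed that selection was not measured.

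**Figure D1:**
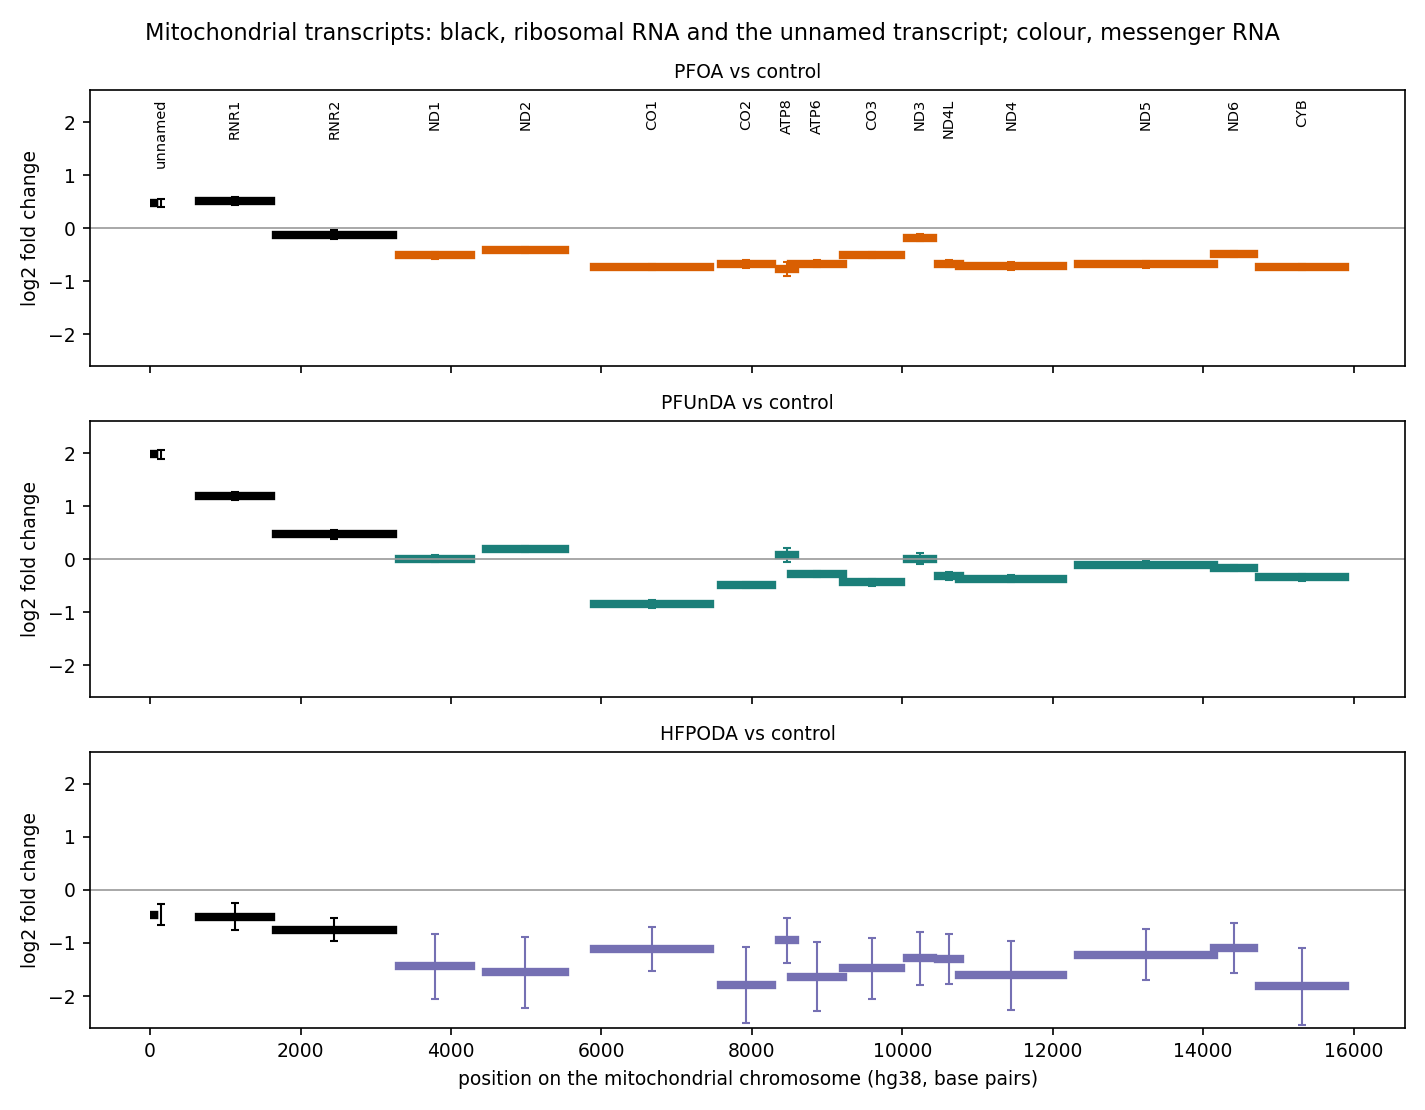
Log2 fold change against control (vertical axis; bars, SE) of transcripts of the mitochondrial chromosome by position in base pairs (horizontal axis, hg38), for PFOA, PFUnDA and HFPODA. MT-RNR1 was at 0.52, 1.198 and -0.50 and MT-CO1 at -0.73, -0.85 and -1.11, and the wide bars of HFPODA include replicate 1, whose mitochondrial share was 0.583%.

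The largest rises with PFUnDA included those of OSGEP, PDGFA, KNG1, FZD1, CYP24A1, ABCC3 and AKNA. KNG1, kininogen, went from 61.2 ± 3.81 to 143 ± 23.5. The largest falls were of HOXD1, RNF187, PIWIL2, DUSP6, G6PC1, CCL20, RAB17 and DEPP1. HOXD1 dropped from 250 ± 48.3 to 54.6 ± 23.1, and RAB17, a small GTPase, from 2048 ± 203 to 836 ± 245. OSGEP and RNF187 ranged within another compound's group by at least 90% of their PFUnDA fold change. OSGEP also ranged by 2.55 on the log2 scale within control, against its fold change of 2.42. RNF187 has 2 further entries of the same protein, with a lowest correlation of -0.199 over 12 libraries. Calls of 4 of the genes named here were lost when single libraries were left out. The limma adjusted p reached 0.136 for OSGEP (without PFUnDA replicates 1, 2 or 3 or control replicates 1 or 3), 0.0797 for PDGFA (PFUnDA replicates 1 or 2 or control replicate 3), 0.103 for FZD1 (PFUnDA replicates 1, 2 or 3 or control replicates 1 or 3) and 0.115 for CYP24A1 (PFUnDA replicates 1 or 2 or control replicates 1, 2 or 3).

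For PFUnDA against control, limma called 972 of 13779 genes, 358 up and 614 down, and 58 changed by at least 1 on the log2 scale. Groups did not overlap in 29.3% of genes, where chance gives 10%. The count was 582 without PFUnDA replicate 1, 366 without PFUnDA replicate 2, 536 without control replicate 1 and 285 without control replicate 3. Of 66 genes named or in the panel, some of them not called to begin with, 21 lost their call in at least 1 fit without a library. The authors' deposited table has 1157 genes past an adjusted p of 0.05, and 888 of them were among the 972. Its companion, the authors' deposited table of pathways, gives DNA replication 20 of the 1268 genes entered, more than the 1157, with 20 of them up (adjusted p = 0.00023), and protein processing in the endoplasmic reticulum 55, of which 48 were down (adjusted p = 0.000262).

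With HFPODA, limma called no single gene, while camera called 7 lists, none of which passed with an estimated correlation. PLIN2 read 9266 ± 472 against 5466 ± 318 in control (SD, n = 3), 1.70-fold, with a log2 fold change of 0.76 (95% interval 0.59 to 0.94) and a limma adjusted p of 0.0764, which no gene went below. CPT1A read 461 ± 26.2 against 305 ± 61.0 (0.61, 0.28 to 0.94, limma adjusted p = 0.148). CDKN1A read 761 ± 44.2 against 1128 ± 83.2 (-0.57, -0.76 to -0.37, 0.0848). All these results include replicate 1, whose mitochondrial messenger share of 0.583% stood apart from 3.19% and 2.28% in the other libraries.

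Hypoxia response genes were higher with HFPODA as a list, 16 of 17 fold changes above 0 and 8 past the threshold adjusted over the list alone (median 0.27, camera adjusted p = 4.6e-05, and adjusted p = 0.306 with an estimated correlation). PFKFB4 read 774 ± 97.0 against 436 ± 20.1, and LOX, lysyl oxidase, 659 ± 142 against 316 ± 77.6. Cholesterol genes were higher, 19 of 22 above 0 and 8 adjusted over the list alone (median 0.25, camera adjusted p = 0.000157, and adjusted p = 0.306 with an estimated correlation), with HMGCS1 at 3839 ± 36.5 against 2922 ± 163. PPAR alpha targets were higher as a list, 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.0254, and adjusted p = 0.306 with an estimated correlation). That call ended without control replicate 1 (0.0815) or control replicate 3 (0.0575).

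Mitochondrially encoded messenger RNAs were lower with HFPODA, 13 of 13 below 0 and 0 adjusted over the list alone. The median was -1.44 (camera adjusted p = 0.000133, and adjusted p = 0.521 with an estimated correlation) and read -0.63 without HFPODA replicate 1, when the list still passed (7.4e-09). MT-CO1 read 82518 ± 43776 against 157020 ± 4051. p53 targets were lower, 6 adjusted over the list alone (median -0.17, camera adjusted p = 0.00315, and adjusted p = 0.364 with an estimated correlation), and so were NRF2 genes, 7 adjusted over the list alone (median -0.17, camera adjusted p = 0.00397, and adjusted p = 0.380 with an estimated correlation). Among these, ZMAT3 read 777 ± 69.0 against 1062 ± 42.4 and AKR1B10 835 ± 61.7 against 1538 ± 353. Inflammatory genes were lower, 2 adjusted over the list alone (median -0.16, camera adjusted p = 0.0254, and adjusted p = 0.306 with an estimated correlation), with CX3CL1 at 3168 ± 229 against 4720 ± 445. The inflammatory call ended without HFPODA replicate 1 (0.0536), HFPODA replicate 3 (0.0783) or control replicate 1 (0.0808).

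For HFPODA against control, limma called 0 of 13751 genes, while 2347 had an unadjusted p under 0.05 where 687.55 would by chance. edgeR and limma-voom called 0 as well, DESeq2 on the recovered reads called 392, limma over all 12 libraries 311 and limma without a filter on low values 57. Groups did not overlap in 26.7% of genes, where chance gives 10%. The limma count was 48 without HFPODA replicate 1, 4 without control replicate 1, and 2 without each of HFPODA replicates 2 and 3 and control replicates 2 and 3. The authors' deposited table has 390 genes past an adjusted p of 0.05, and in the authors' deposited table of pathways complement and coagulation held 21 of the 1008 genes entered, of which 14 were down (adjusted p = 0.0144). More genes were entered there than the 390, so an adjusted p of 0.05 did not select them.

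**Figure D2:**
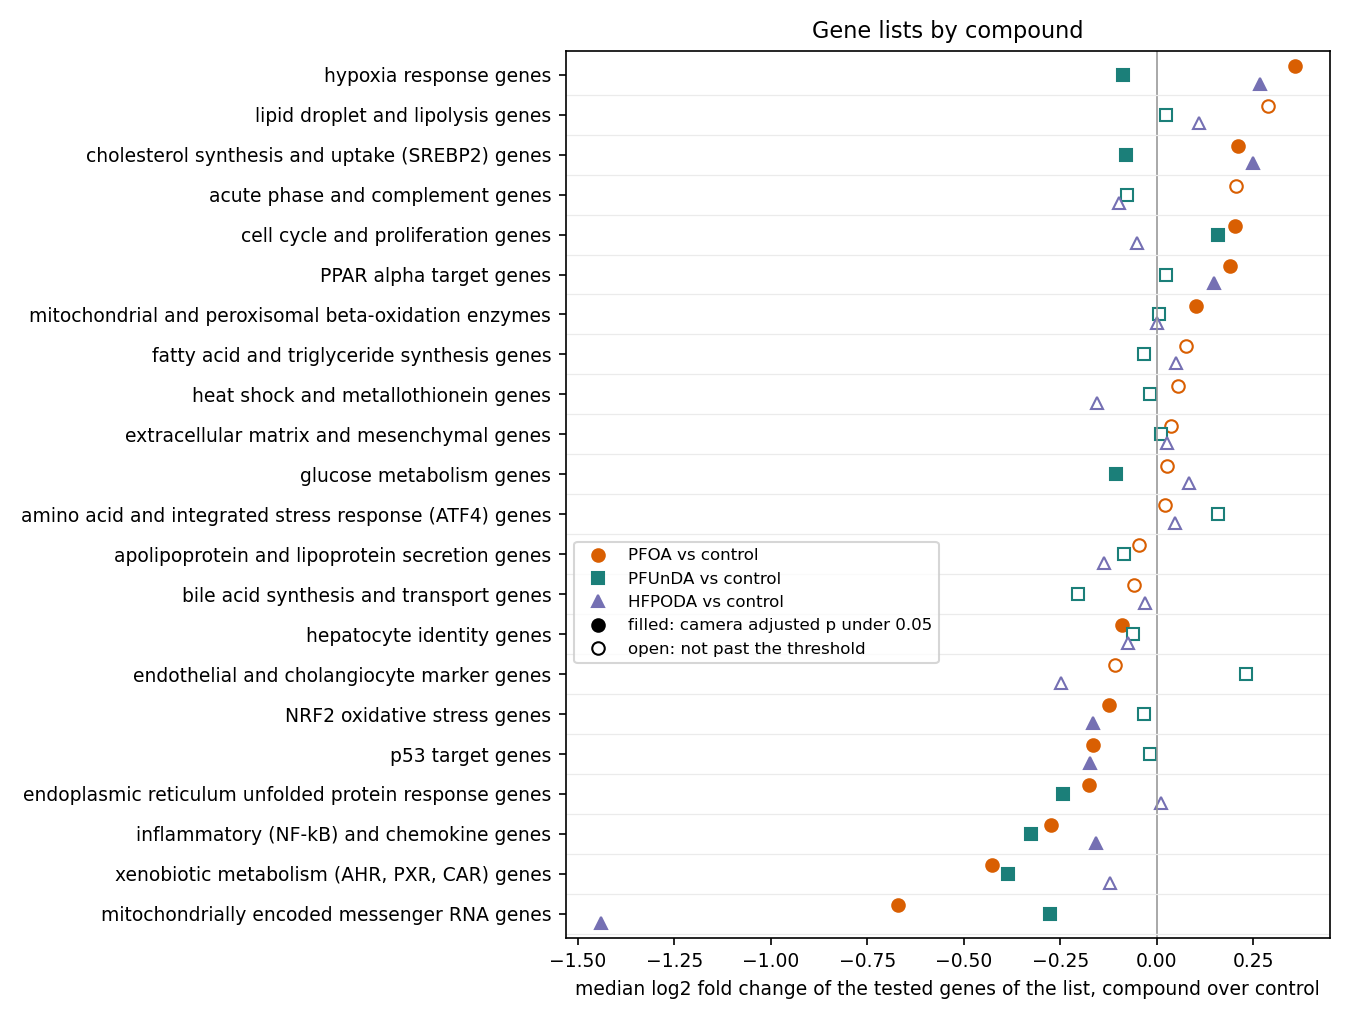
Median log2 fold change against control (horizontal axis) of the tested genes of 22 lists (vertical axis) for PFOA, PFUnDA and HFPODA, with filled symbols for lists past a camera adjusted p of 0.05. Cholesterol genes sat at 0.21, -0.08 and 0.25 and hypoxia response genes at 0.36, -0.09 and 0.27, and the HFPODA value of -1.44 for mitochondrial messenger RNA was -0.63 without replicate 1.

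The acids were then set against one another at the same dose and time. PFUnDA and PFOA share the perfluorinated carboxylic acid structure and differ in chain length. PLIN2 was 4824 ± 345 in PFUnDA and 11568 ± 756 in PFOA (SD, n = 3, jointly scaled reads), 2.40-fold lower, the smallest adjusted p between these compounds (6.5e-06 by limma). BHLHE40, a circadian transcription factor (chromosome 3, 4979437 to 4985323), was 299 ± 34.4 against 838 ± 88.8. FURIN, a proprotein convertase (chromosome 15, 90868588 to 90883564), was higher in PFUnDA, 2131 ± 540 against 837 ± 85.6 (log2 fold change 1.32, SE 0.18, limma adjusted p = 0.00343).

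PPAR alpha targets were lower in PFUnDA than in PFOA in 6 of 20 cases (9 adjusted over the list alone), with FABP1 at 3894 ± 365 against 5830 ± 499 and ACADVL at 2528 ± 23 against 3552 ± 98.0. The list median was -0.23 (camera adjusted p = 0.000119, and adjusted p = 0.0337 with an estimated correlation). Cholesterol genes were lower in 9 of 22 cases (13 adjusted over the list alone; median -0.35, camera adjusted p = 5.7e-10, and adjusted p = 0.0451 with an estimated correlation). HMGCS1 was 2915 ± 383 against 4418 ± 124. These 2 lists were the only ones in any of the 6 comparisons to pass with an estimated correlation. Hypoxia response genes were lower in 9 of 17 cases (10 adjusted over the list alone; median -0.46, camera adjusted p = 5.7e-10, and adjusted p = 0.0548 with an estimated correlation), led by NDRG1 (1986 ± 206 against 3490 ± 194) and BNIP3, a mitophagy receptor (2049 ± 152 against 3028 ± 294).

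Smaller shifts between PFUnDA and PFOA were read in 9 further lists. Lipid droplet genes were lower in 2 of 13 cases, PLIN2 and HSD17B11 (2 down and 1 up adjusted over the list alone; median -0.12, camera adjusted p = 0.0120, and adjusted p = 0.0977 with an estimated correlation). Fatty acid synthesis genes were lower in 2 of 18, ACSS2 and ELOVL6 (7 down and 2 up adjusted over the list alone; median -0.14, camera adjusted p = 0.0120, and adjusted p = 0.325 with an estimated correlation). Beta-oxidation enzymes were lower in 2 of 23, ACADVL and CPT1A (2 adjusted over the list alone; median -0.10, camera adjusted p = 0.0120, and adjusted p = 0.432 with an estimated correlation). Glucose genes were lower in 1 of 17, PGK1 (2 adjusted over the list alone; median -0.18, camera adjusted p = 0.00359, and adjusted p = 0.116 with an estimated correlation). Metallothionein genes MT1E and MT2A accounted for the 2 of 15 heat shock and metallothionein genes that were lower (4 adjusted over the list alone; median -0.06, camera adjusted p = 0.0328, and adjusted p = 0.326 with an estimated correlation). Higher in PFUnDA as lists were ATF4 genes, with NUPR1 the 1 of 22 called (2 adjusted over the list alone; median 0.23, camera adjusted p = 0.00498, and adjusted p = 0.581 with an estimated correlation), and p53 targets, with 0 of 20 (0 adjusted over the list alone; median 0.20, camera adjusted p = 0.00498, and adjusted p = 0.255 with an estimated correlation). So were NRF2 genes, with 0 of 22 (1 adjusted over the list alone; median 0.12, camera adjusted p = 0.00845, and adjusted p = 0.354 with an estimated correlation), and hepatocyte identity genes, with FOXA1 the 1 of 20 (4 up and 1 down adjusted over the list alone; median 0.06, camera adjusted p = 0.0481, and adjusted p = 0.250 with an estimated correlation). Leaving out single libraries ended the calls of beta-oxidation (PFUnDA replicate 1, 0.0998; PFOA replicate 1, 0.110), heat shock (PFUnDA replicate 1, 0.104; PFOA replicate 3, 0.0637) and ATF4 genes (PFOA replicate 1, 0.213). The hepatocyte call ended without PFUnDA replicates 2 (0.126) or 3 (0.0533) or PFOA replicates 1 (0.103), 2 (0.0503) or 3 (0.0592). Among the single genes, NUPR1 (limma adjusted p up to 0.135) and FOXA1 (up to 0.169) lost their calls without any of the 6 libraries, ELOVL6 (up to 0.172) without any but PFUnDA replicate 1, and CPT1A (up to 0.122) without any but PFUnDA replicate 3. PGK1 (up to 0.119) and MT2A (up to 0.189) lost theirs without PFUnDA replicates 2 or 3 or PFOA replicates 2 or 3. So did MT1E (up to 0.0785) without PFUnDA replicate 3 or PFOA replicates 2 or 3, and ACSS2 (up to 0.0961) without PFUnDA replicates 2 or 3 or PFOA replicates 1 or 3.

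Between PFUnDA and PFOA, limma called 486 of 14488 genes, 226 higher and 260 lower in PFUnDA, and 60 by at least 1 on the log2 scale. Upper-quartile scaling gave 152 higher and 303 lower, DESeq2 460 and 406, and limma on the 6 libraries of these groups alone 561 and 429, so which side held more calls depended on the method. The remaining large differences were of TXNIP (1.07), PRSS8 (1.07), TMPRSS2 (1.05) and KNG1 (0.99) above, and PNCK (-1.73), LOX (-1.37) and CA9 (-1.28) below. Without single libraries the count was 96 (PFUnDA replicate 2), 97 (PFUnDA replicate 3), 194 (PFOA replicate 1), 83 (PFOA replicate 2) and 126 (PFOA replicate 3). Among 72 genes named or in the panel, some of them not called to begin with, 19 lost their call in at least 1 such fit. PRSS8 did so without any of the 6 libraries (limma adjusted p up to 0.177), and KNG1 (up to 0.115) and PNCK (up to 0.148) without any but PFUnDA replicate 1. LOX (up to 0.112) and CA9 (up to 0.131) did so without PFUnDA replicates 2 or 3 or PFOA replicates 2 or 3, and TXNIP (up to 0.0669) without PFUnDA replicate 3 or PFOA replicates 2 or 3. The interval of the difference still allowed sizeable shifts for SCD (-0.14, 95% interval -0.33 to 0.06), FASN (-0.12, -0.32 to 0.09), HMOX1 (0.03, -0.20 to 0.26) and CD36 (0.41, -0.04 to 0.86), which did not pass.

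HFPODA, the ether acid, differed from PFOA in G6PC1. It was 338 ± 40.8 in HFPODA and 160 ± 6.04 in PFOA (SD, n = 3), 2.10-fold higher (limma adjusted p = 0.00846, and 0.0553 without PFOA replicate 2), and 314 ± 45.9 in control. SGK1, a glucocorticoid-induced kinase (chromosome 6, 134169248 to 134318112), was 1665 ± 118 against 730 ± 75.1 (log2 fold change 1.19, SE 0.09, limma adjusted p = 0.000212), and DEPP1 2332 ± 206 against 968 ± 61.1. BHLHE40 was lower in HFPODA, 338 ± 81.1 against 838 ± 88.8. For PLIN2 the difference was -0.29 (95% interval -0.45 to -0.13, limma adjusted p = 0.0593) and for CPT1A -0.40 (-0.70 to -0.09, 0.145), so neither of these lipid genes was called different. HFPODA replicate 1, at 0.583% mitochondrial messenger reads, is part of each of these values.

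Cell cycle genes were lower in HFPODA than in PFOA in 4 of 25 cases, MCM7, MCM5, MCM4 and RRM2 (15 adjusted over the list alone; median -0.26, camera adjusted p = 1.6e-08, and adjusted p = 0.384 with an estimated correlation). MCM7 was 3604 ± 43.2 against 4524 ± 32.6, with a limma adjusted p of 0.0196 that went up to 0.0947 without PFOA replicates 1, 2 or 3 or HFPODA replicate 3. The same 4 libraries and, for MCM4 and RRM2, HFPODA replicate 1 ended the calls of MCM5 (up to 0.137), MCM4 (up to 0.154) and RRM2 (up to 0.154). Unfolded protein response genes were higher in 1 of 19 cases, SEL1L at 2297 ± 87.5 against 1871 ± 72.1 (1 adjusted over the list alone; median 0.16, camera adjusted p = 0.0101, and adjusted p = 0.384 with an estimated correlation). Without PFOA replicates 1 or 2 or HFPODA replicate 3 the limma adjusted p of SEL1L went up to 0.102. Mitochondrial messenger RNAs were lower as a list, with 0 of 13 called (0 adjusted over the list alone; median -0.93, camera adjusted p = 0.0101, and adjusted p = 0.872 with an estimated correlation), and this ended without HFPODA replicate 1 (median -0.07, 0.932).

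Between HFPODA and PFOA, limma called 305 of 14488 genes, 199 higher and 106 lower in HFPODA, and 14 by at least 1 on the log2 scale. Upper-quartile scaling gave 128 and 103 and DESeq2 600 and 348, while limma on the 6 libraries of these groups alone called 3 genes. The further large differences were of KLF9 (0.86) and MARCHF8 (0.79) above, and of HAMP, the iron hormone hepcidin (-0.98), CYP24A1 (-0.94), IFT22 (-0.88) and SLC51B, a bile acid carrier subunit (-0.85), below. Left-out libraries ended the calls of MARCHF8 (up to 0.111), CYP24A1 (up to 0.128) and IFT22 (up to 0.0996) in the cases of HFPODA replicate 3 and PFOA replicates 1, 2 and 3, and those of HAMP (up to 0.150) and SLC51B (up to 0.146) also for HFPODA replicate 1. The count was 888 without HFPODA replicate 2, 63 without HFPODA replicate 3, 21 without PFOA replicate 1, 11 without PFOA replicate 2 and 56 without PFOA replicate 3.

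HFPODA and PFUnDA differed in PLIN2 and G6PC1. PLIN2 was 9449 ± 488 in HFPODA against 4824 ± 345 in PFUnDA (SD, n = 3), 1.96-fold higher (limma adjusted p = 4.8e-05). G6PC1 was 338 ± 40.8 against 121 ± 21.7, 2.79-fold higher (limma adjusted p = 0.000213), with control at 314 ± 45.9. LFNG, a glycosyltransferase of Notch signalling (chromosome 7, 2512529 to 2529177), was 90.3 ± 1.42 against 24.0 ± 9.75, and IGFBP1, a secreted binding protein for insulin-like growth factors (chromosome 7, 45888360 to 45893660), 15472 ± 3581 against 4344 ± 1227. SLC6A12, a betaine transporter (42.4 ± 21.1 against 167 ± 58.9), ERP27 (27.0 ± 7.82 against 83.0 ± 6.52) and FURIN (760 ± 149 against 2131 ± 540) were lower in HFPODA. Replicate 1 of HFPODA, with its mitochondrial messenger share of 0.583%, is among these libraries.

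Hypoxia response genes were higher in HFPODA than in PFUnDA in 12 of 17 cases (13 adjusted over the list alone), including P4HA1 (2596 ± 31.5 against 1724 ± 87.3) and CA9, carbonic anhydrase IX (92.2 ± 31.6 against 30.3 ± 3.94). The list median was 0.45 (camera adjusted p = 2.3e-08, and adjusted p = 0.0896 with an estimated correlation). Cholesterol genes were higher in 9 of 22 cases (11 adjusted over the list alone; median 0.27, camera adjusted p = 8.4e-07, and adjusted p = 0.0896 with an estimated correlation), with CYP51A1 at 765 ± 255 against 355 ± 35.5. PPAR alpha targets were higher in 6 of 20 cases (7 adjusted over the list alone; median 0.25, camera adjusted p = 0.00366, and adjusted p = 0.0896 with an estimated correlation), with ANGPTL4 at 42.6 ± 5.34 against 15.3 ± 4.02. Glucose genes were higher in 3 of 17 cases (6 adjusted over the list alone; median 0.27, camera adjusted p = 0.00114, and adjusted p = 0.107 with an estimated correlation), among them SLC2A1 at 18151 ± 2961 against 10866 ± 943. Lipid droplet genes were higher in 4 of 13 cases (4 adjusted over the list alone; median 0.26, camera adjusted p = 0.0434, and adjusted p = 0.144 with an estimated correlation), with HSD17B11 at 2959 ± 66.0 against 2043 ± 64.9. Without HFPODA replicates 1 (0.0814) or 2 (0.0810) or PFUnDA replicates 1 (0.0698) or 3 (0.0776) the lipid droplet call ended.

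Cell cycle genes were lower in HFPODA than in PFUnDA in 7 of 25 cases (10 adjusted over the list alone; median -0.20, camera adjusted p = 2.3e-05, and adjusted p = 0.245 with an estimated correlation), with MCM5 at 2027 ± 273 against 3094 ± 190 and E2F1, a transcription factor of S phase entry, at 1233 ± 96.9 against 1738 ± 62.5. p53 targets were lower in 5 of 20 cases (7 down and 1 up adjusted over the list alone; median -0.13, camera adjusted p = 0.0434, and adjusted p = 0.318 with an estimated correlation), with the apoptosis gene BAX at 1320 ± 89.7 against 1753 ± 105. NRF2 genes were lower in 3 of 22, FTL and TXN among them (10 adjusted over the list alone; median -0.20, camera adjusted p = 0.00291, and adjusted p = 0.290 with an estimated correlation). Mitochondrial messenger RNAs were lower as a list, with 0 of 13 called (12 adjusted over the list alone; median -1.25, camera adjusted p = 0.000412, and adjusted p = 0.433 with an estimated correlation, with a median of -0.45 without HFPODA replicate 1). Unfolded protein response genes were higher in 6 of 19 cases (10 up and 1 down adjusted over the list alone; median 0.17, camera adjusted p = 0.00291, and adjusted p = 0.144 with an estimated correlation), with the chaperone HSPA5 at 22187 ± 3433 against 16627 ± 476. Inflammatory genes were higher in 3 of 12, TNFAIP3, BIRC3 and NFKB2 (4 up and 1 down adjusted over the list alone; median 0.26, camera adjusted p = 0.0434, and adjusted p = 0.144 with an estimated correlation). The p53 call ended without HFPODA replicate 2 (0.178) or PFUnDA replicate 3 (0.144), and the inflammatory call without HFPODA replicates 2 (0.140) or 3 (0.0598) or PFUnDA replicate 1 (0.110). Single libraries also ended the calls of HSPA5 (limma adjusted p up to 0.0596, PFUnDA replicates 1, 2 or 3), FTL (0.111, PFUnDA replicates 1, 2 or 3), TXN (0.136, all libraries but HFPODA replicate 3), BIRC3 (0.107, all but PFUnDA replicate 2) and NFKB2 (0.136, all 6).

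**Figure D3:**
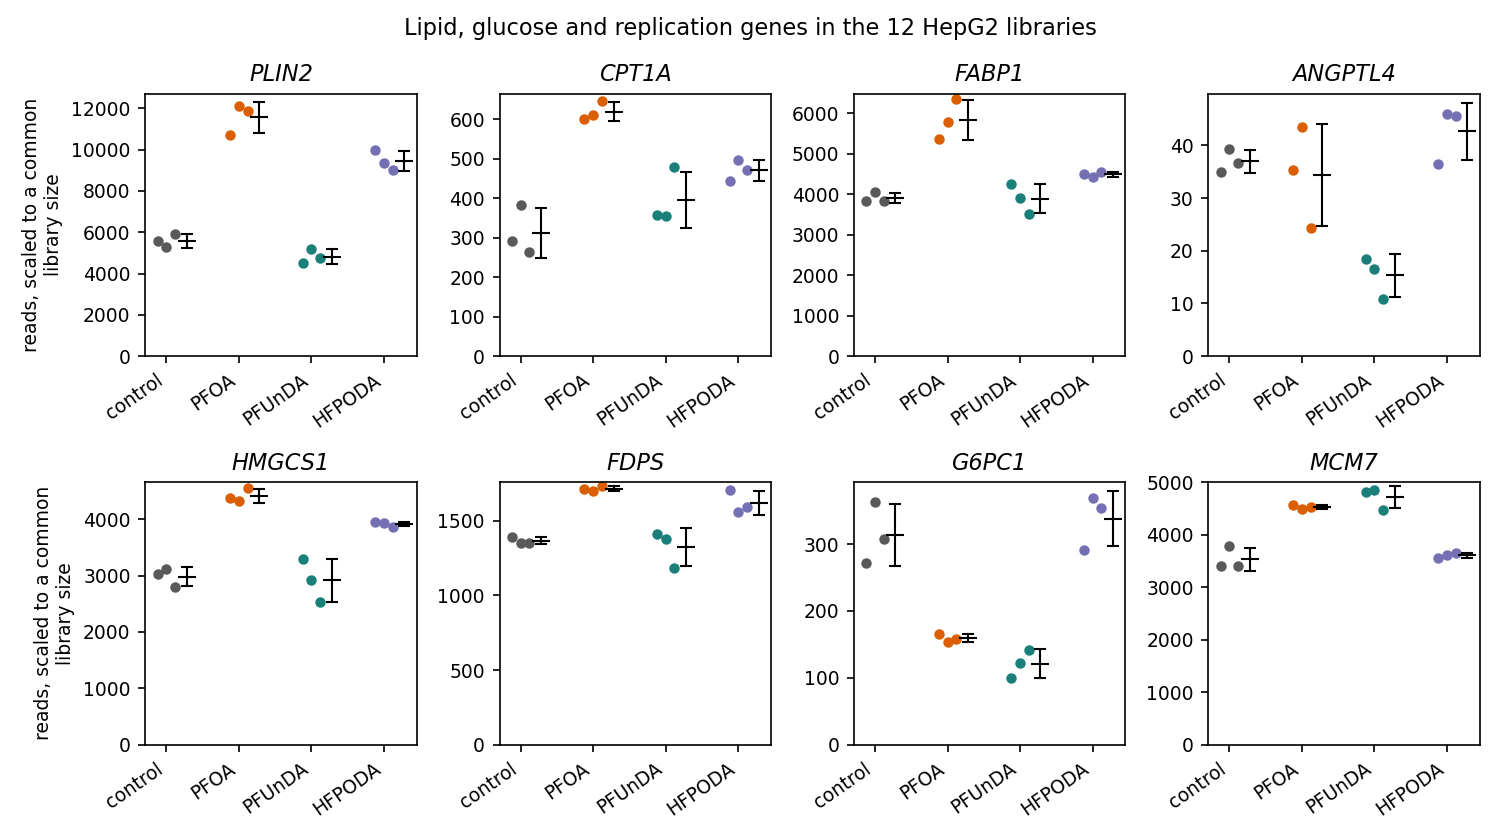
Jointly scaled reads per library (vertical axis, points; bars, mean ± SD of 3 libraries) of 8 lipid, glucose and replication genes in control, PFOA, PFUnDA and HFPODA (horizontal axis). PLIN2 averaged 5581, 11568, 4824 and 9449 reads in these groups, and G6PC1 314, 160, 121 and 338.

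Between HFPODA and PFUnDA, limma called 1469 of 14488 genes, 788 higher and 681 lower in HFPODA, and 119 by at least 1 on the log2 scale. On the 6 libraries of these groups alone limma called 291, against 990 for PFUnDA against PFOA and 3 for HFPODA against PFOA, so the order of the counts between compounds depended on the model. Groups did not overlap in 29.4% of genes here, in 23.4% for HFPODA against PFOA and in 29.5% for PFUnDA against PFOA, where chance gives 10%. Other large differences were of LOX (1.54) and PNCK (1.54) above, and of ODAM (-1.48) and GPX2, a glutathione peroxidase (-1.47), below. Of these, PNCK was not called without HFPODA replicate 1 or PFUnDA replicates 2 or 3 (limma adjusted p up to 0.0771), and ODAM (up to 0.0910) and GPX2 (up to 0.0683) were not without PFUnDA replicates 2 or 3. More were lower than higher with protein-coding genes alone (823 and 816), with array quality weights (1634 and 1571) and without HFPODA replicate 2 (1270 and 1057), and the count was 2327 without that library, 918 without PFUnDA replicate 1, 518 without PFUnDA replicate 2 and 730 without PFUnDA replicate 3.

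PFUnDA and PFOA changed 502 genes in the same direction against control, 126 up and 376 down, among 13591 tested in both, and 5 in opposite directions. Independent lists of those sizes would share 18.6 up and 57.6 down. Groups simulated without an effect against the shared controls shared at most 1 gene in 20 draws. Such groups had no true changes to share, so that value is no yardstick for the 502, and compounds with unrelated effects were not simulated. The correlation of their log2 fold changes across genes, which are not independent replicates, was 0.572 (0.515 simulated), and the covariance was 0.0754 (0.0391 simulated). HFPODA and PFOA shared 0 calls, since limma called 0 genes for HFPODA, yet their covariance was 0.0978 (0.0389 simulated, correlation 0.654 against 0.514). For HFPODA and PFUnDA the covariance was 0.0561 (0.0392 simulated) and the correlation 0.439, under each of the 20 draws (0.514 simulated, lowest 0.488). The 3 controls are too few to split, so part of any excess over the independent expectation may come from the controls that the comparisons share. The simulation drew genes independently, so its draws lack variation shared across genes and spread too little to judge these covariances and correlations.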

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

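TMM scaling, edgeR with TMM, array quality weights, edgeR without mitochondrial genes and edgeR without HFPODA replicate 1 were chosen after the data were seen, as were, between compounds, pseudocounts 0.1 and 10 and a filter at 50. Of the counts of genes and lists, 148 stayed within 1.5 times the main count and 66 moved further. Of the list results under all alternative settings, most of them fixed in advance, 1334 kept their side of the threshold, 27 came past it and 103 fell short of it, and of the named genes 7453, 207 and 424 did. Of results called in either of the 2 settings compared, 0 changed direction, while some genes that were called in neither did. The 7453 include HAMP and SLC51B for HFPODA against PFOA, to which DESeq2 gave no adjusted p. Where no value shows it, the cause was not tested. Depth limits genes with low counts, which fold changes on log2(value + 1) understate.

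Requiring an absolute log2 fold change of at least 1 left 175 of 2006 genes for PFOA, 58 of 972 for PFUnDA, 60 of 486 for PFUnDA against PFOA, 14 of 305 for HFPODA against PFOA and 119 of 1469 for HFPODA against PFUnDA, and 17 of the 502 genes shared by PFUnDA and PFOA. DESeq2 called 392 genes for HFPODA where limma called 0, 866 for PFUnDA against PFOA and 948 for HFPODA against PFOA. With DESeq2, HFPODA shared 287 genes with PFOA and 130 with PFUnDA. Without a filter the counts were 57 for HFPODA, 284 for PFUnDA against PFOA and 134 for HFPODA against PFOA. Protein-coding genes alone gave 16 for HFPODA, and a filter at a CPM of 5 gave 483 for HFPODA against PFOA.

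With all 12 libraries in 1 model the count was 1239 for PFOA and 311 for HFPODA. With only the 6 libraries of the 2 groups it was 990 for PFUnDA against PFOA, 3 for HFPODA against PFOA and 291 for HFPODA against PFUnDA. Array quality weights gave 1928 for PFUnDA, 2480 for HFPODA, 1693 for PFUnDA against PFOA, 1605 for HFPODA against PFOA and 3205 for HFPODA against PFUnDA, and these fits gave convergence warnings. edgeR without HFPODA replicate 1 called 28 for HFPODA.

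Leaving out each library in turn gave 901 to 1848 genes for PFOA, 285 to 1028 for PFUnDA, 2 to 48 for HFPODA, 83 to 476 for PFUnDA against PFOA, 11 to 888 for HFPODA against PFOA and 518 to 2327 for HFPODA against PFUnDA. The lists called ran from 5 to 9 for PFUnDA and from 3 to 5 for HFPODA against PFOA. With an estimated correlation, camera called 0 lists for PFOA, 0 for PFUnDA, 0 for HFPODA, 2 for PFUnDA against PFOA, 0 for HFPODA against PFOA and 0 for HFPODA against PFUnDA. The fry test called 5 lists for PFUnDA and 11 for HFPODA.

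The labels give each group replicates 1, 2 and 3 without saying that a number marks a shared day or culture. Deviations of libraries with the same number correlated at -0.067 to 0.0546. With a replicate block the counts were 1173 for PFOA, 973 for PFUnDA, 0 for HFPODA, 369 for PFUnDA against PFOA, 175 for HFPODA against PFOA and 1453 for HFPODA against PFUnDA.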

Other observations

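The tests of scaling, of no effect of HFPODA and of near-identical copies, and the choice of the single genes given first, those of opposite direction and HAGLR, came after the results were seen, and the histone test was chosen after a first test had failed but before histone values were seen. Several genes of lists that were not called changed with both PFOA and PFUnDA, and they stand here as single genes. NR0B2, a repressor induced by bile acid signalling, fell from 1566 ± 107 to 974 ± 64.5 with PFOA (SD, n = 3; limma adjusted p = 0.000731) and from 1584 ± 107 to 876 ± 42.7 with PFUnDA (0.000549). ABCB4, which exports phospholipid into bile, fell by 0.47 and by 0.54 on the log2 scale. MTTP, which loads lipid onto apolipoprotein B, fell by 0.44 and by 0.45. The zinc exporter SLC30A1 fell by 0.49 and by 0.55 with PFOA and PFUnDA. KRT19, a keratin of bile duct cells, rose by 0.42 and 0.75, while SOX9, another marker of those cells, fell by 0.38 and by 0.30. FN1, fibronectin, fell by 0.78 and by 0.44, and the complement component C5 rose by 0.46 and 0.61.

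PFOA and PFUnDA moved 5 genes in opposite directions, NDRG1 (0.31 and -0.50), CP, which encodes ceruloplasmin (0.25 and -0.27), FOXQ1 (-0.25 and 0.30), TUBB1 (0.62 and -0.57) and MYSM1 (0.28 and -0.37). HOXD1 read -1.94 with PFOA, -2.26 with PFUnDA and -1.64 with HFPODA, and the neighbouring non-coding gene HAGLR -1.04, -0.96 and -1.03, of which limma called the values of PFOA and PFUnDA. Whether counting used strand is not stated, so overlapping reads of neighbours are not excluded.

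With PFUnDA, MT-RNR1 and MT-RNR2 were higher, while 7 of 13 mitochondrial messenger RNAs were called lower and 4 of the 13 read above 0. That messenger list did not pass camera with an estimated correlation (adjusted p = 0.569). An unnamed transcript at positions 1 to 289 of the mitochondrial chromosome rose more than either ribosomal RNA, by 1.98 on the log2 scale (limma adjusted p = 3.6e-05). It read 0.47 with PFOA (limma adjusted p = 0.00643) and -0.47 with HFPODA (0.284). A scaling error would move ribosomal and messenger RNA alike, and so cancels in their difference. MT-RNR1 minus MT-CO1 was 2.05 (SE 0.142) on the log2 scale. That pair was chosen after the values were seen, and MT-CO1 fell most of the 13 messages, so the difference restates the pattern. It shows only that scaling alone did not part these 2 transcripts. Weaker poly(A) selection would raise replication-dependent histone messages too. The median of the 11 tested was -0.25 (SE 0.167), against 0.599 for 0.5 times the change of MT-RNR1. That SE came from resampling the 11 genes, which are not replicates, and holds no spread between libraries. The histone test replaced one on nuclear non-coding RNAs, of which 2 of 39 were tested (-0.48 and -0.08), too few to decide. Histone messages also hold a polyadenylated fraction of unknown size. A change in mitochondrial RNA processing or decay stays a hypothesis, and no biological cause was tested.

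For HFPODA, limma called 0 genes, and 3 explanations were tested. If replicate 1 alone hid an effect the size of PFOA's, leaving it out would restore a large count, and the count without it was 48, although array quality weights, in a fit with convergence warnings, gave 2480. If depth were the cause, thinning would end the calls of PFOA. With every library thinned to 13029730 reads, the fewest called over 10 draws was 1912. PFOA libraries held only 13801065 to 14637488 reads before thinning, so few reads were removed. The result shows only that this small gap in depth did not end the calls. If HFPODA had no effect, the covariance of its fold changes with those of PFOA would stay near the simulated level, and it was 0.0978 against at most 0.0422. The simulation drew each gene independently, without variation shared across genes within a library, so it cannot decide this. For an effect the size of PFOA's, the tables argue against replicate 1 and against this gap in depth, each as the whole account. A smaller effect that either could hide was not tested. The tables leave open whether HFPODA had no effect. Part of the lack of calls may lie with replicate 1, since its pairs differed by a chi-square per degree of freedom of 48.7 and 30.6, against 9.11 for replicates 2 and 3.

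Among the 16 genes with the largest PFOA changes, 6 ranged within another compound's group by at least 90% of their fold change, a share set after the ranges were seen in place of a stricter one that gave 4 of 16. Reads divided between near-identical copies would vary in opposite directions between them. For ACACA the lowest correlation with a second entry of the same protein was -0.442 over 12 libraries, which cannot be told apart from chance or copies at this number, and the interval behind that reading was required only after the value was seen. The other 5 (CUTA, RNH1, FLII, GLP2R and CLSTN3) have no second entry in the tables, so copies cannot be told apart from variation of the genes themselves. Wide ranges were not confined to treated groups, since of 10839 genes 124 ranged over more than 2 on the log2 scale in control, 134 in PFOA, 136 in PFUnDA and 161 in HFPODA.

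Splitting the 6 libraries of each comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. Against control, 1 of 10, the real split, gave as many calls for PFOA (2006, highest other 3) and PFUnDA (972, highest other 5), and all 10 of 10 did for HFPODA (real 0, highest other 4). Between compounds the 6 libraries were regrouped with the other 6 kept in the model, and 1 of 10, the real split, gave as many for PFUnDA against PFOA (486, highest other 1), HFPODA against PFOA (305, highest other 3) and HFPODA against PFUnDA (1469, highest other 1). With the 6 libraries alone in the model, 1 of 10 did for PFUnDA against PFOA (990, highest other 5) and HFPODA against PFUnDA (291, highest other 1), but 2 of 10 for HFPODA against PFOA (real 3, highest other 4).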
